A study of Mus musculus with 6 samples.

How the data were processed

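Total RNA from back skin of mouse embryos at e18.5 was hybridised to 6 oligonucleotide arrays, 1 per mouse, from 3 Get1 +/+ and 3 Get1 -/- animals. Get1 is the earlier name of grainyhead-like 3 (Grhl3), per the labels. Per the labels' protocols, RNA was extracted with TRIzol and spin columns, converted to cDNA with an oligo(dT) primer that carries a T7 promoter, and transcribed into biotin-labelled cRNA. The deposited values are linear signal intensities, and MAS5 is the processing tool named by the labels, with no version given. The deposited table holds 45101 probe sets, 64 of them controls, and no detection calls. The 2% trimmed mean came to 500 on every array, so the deposited intensities were already scaled to one another, and no further scaling was applied. The number of arrays limits the precision of every value below.

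The values were turned into log2, the 64 control probe sets were left out, and probe sets whose mean log2 value over the 6 arrays lay at or above the median (a signal of 137) were kept, which left 22519 of 45037. Among the 45037, 34945 carried 1 gene symbol, 932 several and 9160 none in the platform annotation, so these last are unnamed here. Entrez identifiers of 99.4% of the probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 of the symbols. That table was used for names and for the order of neighbouring genes alone, because the deposited table names no genome build. Each gene was represented by its kept probe set with the highest mean, among those naming that gene alone, which gave 11387 genes.

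Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit on the groups, eBayes with a mean-variance trend, two-sided), and p was adjusted by Benjamini-Hochberg over all probe sets or genes tested. The threshold was an adjusted p under 0.05. Standard errors (SE) and 95% intervals are those of this model. Lists of genes with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, beside camera with the correlation estimated for each list and the rotation test fry. At the preset correlation camera takes its degrees of freedom from the number of genes, and with an estimated correlation from the arrays. For members of a list, p was also adjusted over the list alone. The 28 lists, the tests, the filter, the threshold and the alternatives, except those named below as added, were fixed before the data were examined. The lists of other cell types covered dermal fibroblast and matrix, skeletal muscle, adipocyte, endothelium, erythroid, macrophage and lymphoid, mast cell, melanocyte, and Schwann cell and nerve genes. The sex-linked genes served as a check and were not tested as a list. The uroplakin list (1 measured gene) and the list of hair keratins and Krtap genes (4) were too short to test. The result of 1 tested list is not reported here, and it is included in the counts of lists.

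The genes named were chosen by a rule fixed in advance. It takes Grhl3, up to 12 genes with the largest changes per direction among those past the threshold whose genotypes do not overlap, and, where fewer than 12 pass, up to 6 more with the smallest unadjusted p in that direction. It adds up to 4 members per list with the smallest p, any other member that passes over all genes or over the list alone, and the sex-linked genes. Khdrbs1, Ptp4a2, the Sprr2a probe sets and the neighbours of Grhl3 fall outside the rule and were chosen after their values were seen, as were the genes of an added list of other epithelium and an added list of neutrophil genes.

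The labels number the mice 1 to 3 in each genotype and name no shared litter, batch or day. Over the 22519 kept probe sets, deviations from the genotype means of mice with the same number correlated at 0.133, 0.26 and 0.14, all above the limit of 0.1 set for treating the numbers as pairs, and all 6 arrays correlated best with their own number. The deviations of the 3 arrays of a genotype sum to 0, so these 6 matches are not independent and are weak evidence of pairing. Over the 11387 genes these correlations were -0.0195, 0.361 and -0.0251, so 1 of the 3 pairs passed the limit. Over all 45037 probe sets 0 of the 3 passed it, and under the stricter filter 2 did. The pairing therefore depends on the table. The table of kept probe sets, that of the first comparison, was taken for this check after the counts of the fit with a replicate block were already known, so the choice was not blind to them. The unpaired fit fixed in advance stays the main one, and values with the block are given beside the counts they move.

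Alternatives were quantile normalization, median centring, no filter, a stricter filter at the 70th percentile, an offset of 37.6 (the 25th percentile of the deposited values) before log2, eBayes without the trend, array weights, the replicate block, each array left out in turn, the mean of a gene's kept probe sets, camera with an estimated correlation, fry, and a threshold of 0.1. The filter was computed over all 6 arrays when 1 was left out. A block for a split of the arrays seen in the control probe sets, and a fit without the 100 RefSeq genes on either side of Grhl3, were added after seeing the data.

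The code was tested on simulated data made from the means and spreads of the 22519 kept probe sets, with 200 changed probe sets in each of 5 simulations of 3 arrays against 3. Of the simulated 2-fold changes 31.2% were recovered, of the 4-fold changes 77.9% and of the 16-fold changes 97.6%, and 3.25% of all calls were false. The noise was drawn independently for each probe set. The 5 simulations gave 708 calls together, while the genotypes gave 6 probe sets, so these rates need not hold for the data. In 20 simulations of the 11387 genes, without correlation between genes, camera found a list of 25 genes shifted by 0.5 on the log2 scale in all 20 and called an unshifted list in 1.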

Results

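Expression was measured in the same region of back skin from 3 Get1 +/+ and 3 Get1 -/- mice at e18.5, when the epidermal barrier is being completed. Get1, now named Grhl3, encodes a grainyhead-like transcription factor, and the comparison asks which transcripts depend on it in this tissue. Values are MAS5 signals scaled to the same mean on each array, in arbitrary units, with group means ± SD (n = 3 per genotype). Correlations between arrays over the kept probe sets ran from 0.916 to 0.971. The highest correlation between genotypes was 0.971, between Get1 +/+ replicate 1 and Get1 -/- replicate 3, and the lowest within a genotype was 0.94.

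The only probe set for Grhl3 read 694 ± 229 in Get1 +/+ and 346 ± 88.5 in Get1 -/- skin. All 3 Get1 -/- values (246, 413 and 380) lay below all 3 Get1 +/+ values (478, 934 and 670). The log2 change was -0.98 ± 0.28 (SE), and its adjusted p of 0.497 over all genes missed the threshold. The labels do not state which part of the gene was deleted, and a probe set outside that part checks nothing about the genotype.

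In Get1 -/- skin 3 genes rose and 2 fell past the threshold, of 11387 tested with limma. Krt6b, a keratin of wounded and hyperproliferative epidermis, rose from 146 ± 35.4 to 18748 ± 4099, a log2 change of 7.01 ± 0.22 (adjusted p = 1.11e-06). Rptn, which encodes the cornified envelope protein repetin, rose from 143 ± 66.5 to 3964 ± 2148, a log2 change of 4.78 ± 0.41 (adjusted p = 0.00293). The other Rptn probe sets, left out by the filter for their low signal, did not follow and changed by 0.68 and -0.95. Sprr2d, a small proline-rich envelope precursor, rose from 747 ± 198 to 5236 ± 691, a log2 change of 2.84 ± 0.21 (adjusted p = 0.00138). Gsta2, a glutathione transferase, fell from 1655 ± 103 to 465 ± 101, a log2 change of -1.85 ± 0.18 (adjusted p = 0.00756). Krt77, a suprabasal keratin, fell from 545 ± 193 to 92.4 ± 18.3, a log2 change of -2.51 ± 0.31 (adjusted p = 0.0404). In each of these 5 genes all 3 arrays of one genotype lay above all 3 of the other. The low values of Krt6b, Rptn and Krt77 lie in a range where probe sets of silent genes read, so the sizes of these 3 changes may be underestimates. Gsta2 missed the threshold without Get1 +/+ replicate 3 (adjusted p = 0.0682). Krt77 missed it in 8 of 16 alternatives, among them leaving out Get1 +/+ replicate 2 (0.134) or 3 (0.375), or Get1 -/- replicate 1 (0.114), 2 (0.0806) or 3 (0.129).

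**Figure D1:**
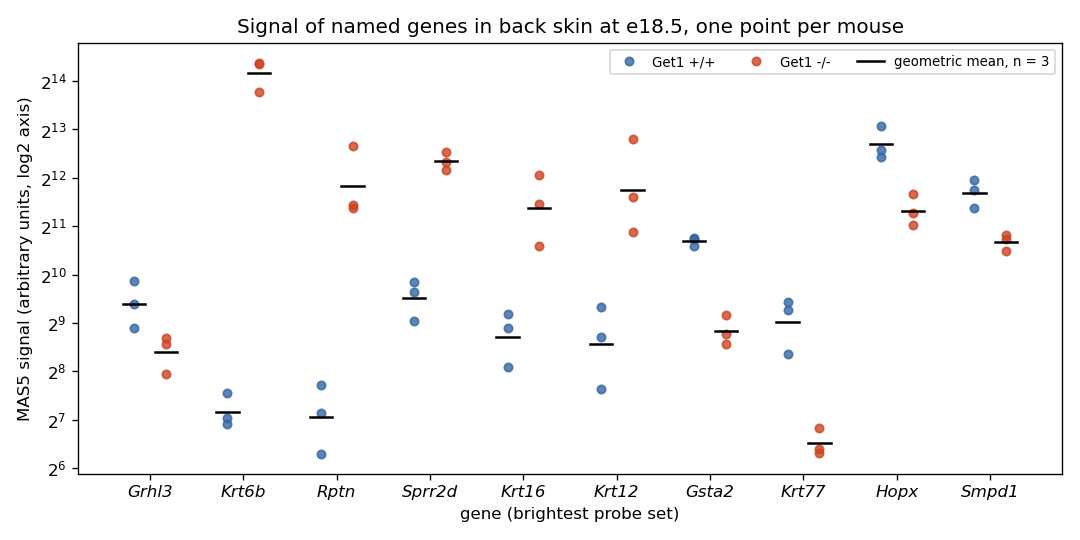
MAS5 signal (arbitrary units, log2 axis) of 10 named genes, with 1 point per mouse and bars for geometric means (n = 3 per genotype). Krt6b lies between 121 and 186 in Get1 +/+ and between 14024 and 21364 in Get1 -/- skin.

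The 6 genes with the next smallest p in each direction did not pass over all genes in the unpaired fit. Higher values in Get1 -/- skin were those of Rbp7 (log2 change 1.86 ± 0.26), Krt16, the type I partner of the Krt6 keratins (2.65 ± 0.38, adjusted p = 0.0884), Krt12, a keratin known from the cornea (3.20 ± 0.51), Stfa2l1 (1.23 ± 0.21), Lce3c (2.20 ± 0.39) and Lgi2 (1.19 ± 0.21). Lower values were those of Zfp593 (-1.50 ± 0.22), Gdpd3 (-1.58 ± 0.24), Slc46a2 (-2.14 ± 0.33), Hopx, a homeodomain protein of differentiating epidermis (-1.38 ± 0.21), the aldehyde oxidase Aox4 (-1.33 ± 0.21) and Rnf227 (-1.0 ± 0.16). Their adjusted p in that fit ran from 0.0787 for Rbp7 to 0.187 for Lgi2. With the replicate block, whose pairing is uncertain, Rbp7 (0.0494), Stfa2l1 (0.0365), Gdpd3 (0.0413), Slc46a2 (0.0134) and Aox4 (0.0365) passed. Krt16, Krt12 and Hopx passed there too, and Lce3c, Lgi2, Zfp593 and Rnf227 did not. Zfp593 lies among the 100 genes on either side of Grhl3, where changes were more frequent than elsewhere and variants carried along with the targeted locus were not excluded. Its other probe set, left out by the filter for its low signal, changed by -0.69. There the Get1 -/- values (60.5 to 78.7) lay below the Get1 +/+ values (88.7 to 138). Both Krt12 probe sets were higher in Get1 -/- skin, by 3.20 and 3.52 on the log2 scale.

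At the level of probe sets 6 of 22519 passed, 4 higher and 2 lower. They were the probe sets of Krt6b, Sprr2d, Rptn and Gsta2, a probe set that Sprr2a1, Sprr2a2 and Sprr2a3 share and that rose from 3597 ± 985 to 17800 ± 3656, and 1 of 5 kept Khdrbs1 probe sets. This last one fell by 2.50 on the log2 scale, from 3180 ± 704 to 552 ± 48.4, while the other kept Khdrbs1 probe sets changed by between -0.50 and 0.15 and did not pass. At an unadjusted p under 0.05 there were 1514 probe sets and 931 genes, where 1126 and 569.4 are expected with no change. Other splits of the 6 arrays into 3 and 3 gave up to 2760 probe sets and 1411 genes, and 3 of these 9 gave more probe sets and 2 more genes than the genotypes, so these counts alone show no excess due to genotype. Genotypes did not overlap in 11.98% of genes, where chance gives 10%.

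The counts depended on single arrays and on the block. Without Get1 +/+ replicate 1 the counts were 25 probe sets and 120 genes, and without Get1 +/+ replicate 3 they were 5 and 3. With the replicate number as a block they were 35 probe sets and 44 genes (12 genes higher, 32 lower), including all 5 genes above and Krt16 (adjusted p = 0.0251), Krt12 (0.000606), Hopx (0.0113), Lce1m (0.0306), Gsdma (0.0247) and Smpd1 (0.0434). Other list members that passed with the block were Klk5 (0.0365), Krt23 (0.0247), Dgat2 (0.0494) and Tnnc1 (0.0474). Whether the numbers pair the mice differed between the table of probe sets and that of genes.

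Of 25 gene lists tested, camera at the preset correlation placed 12 lower and 5 higher in Get1 -/- skin, and with an estimated correlation it called 0 (smallest adjusted p = 0.351). The directional test of fry also called 0 (smallest adjusted p = 0.228), and its test for change in either direction called 4, the stress keratins and alarmins (9.48e-05), the Sprr family (0.00164), macrophage and lymphoid genes (0.0187) and envelope proteins (0.0191). The stress keratin, Sprr and envelope lists hold Krt6b, Sprr2d and Rptn, which passed alone, and a few such members can carry that test. The directional fry had 4 lists at an unadjusted p under 0.05 and there was 1 in camera with the estimated correlation. The shifts below are therefore directions shared by many members, most of which did not pass alone. Members of many lists vary together, so counts of members higher or lower are not independent evidence. Averaged over members, genotypes did not overlap for the suprabasal, basal keratinocyte, junction, Sprr, and macrophage and lymphoid lists. They overlapped for the other lists called at the preset correlation. For barrier lipid genes the mean log2 deviation was 0.0733 in Get1 -/- replicate 2 and -0.0341 in Get1 +/+ replicate 1.

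Barrier lipid genes had a median log2 change of -0.55, with 35 of 40 measured members lower (camera adjusted p = 1.08e-11, and adjusted p = 0.351 with an estimated correlation). Without Get1 +/+ replicate 2 the median was -0.32. Over all genes 0 of them passed, and adjusted over the list alone 4 fell. These were the acid sphingomyelinase Smpd1 (-1.01 ± 0.18), the very long chain fatty acid elongase Elovl1 (-0.72 ± 0.15), Dgat2 (-0.84 ± 0.19) and the serine palmitoyltransferase subunit Sptlc3 (-1.11 ± 0.29). The other kept probe sets of Elovl1 and Dgat2 followed at an unadjusted p under 0.05 (limma), and that of Smpd1 did not. Cholesterol synthesis genes had a median of -0.25, with 18 of 19 lower (adjusted p = 9.4e-06, and 0.351 as the adjusted p with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Their median was -0.40 without Get1 +/+ replicate 1, and their smallest p was that of Dhcr7 (-0.74 ± 0.23).

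Junction genes had a median log2 change of -0.31, with 24 of 25 lower (adjusted p = 2.09e-09, and adjusted p = 0.351 with an estimated correlation), and 7 fell adjusted over the list alone. They included the claudins Cldn4 (-1.10 ± 0.25) and Cldn23 (-1.88 ± 0.52), occludin Ocln (-1.10 ± 0.35) and Nectin4 (-0.89 ± 0.20), beside Crb3, Gjb2 and Cgn. Genotypes overlapped for Ocln and Gjb2. The other kept probe sets of Nectin4, Ocln and Crb3 did not follow at an unadjusted p under 0.05 (limma), and the remaining genes had no other kept probe set. With the stricter filter the median of the junction genes was -0.18. Suprabasal keratin and desmosome genes had a median of -0.20 (adjusted p = 1.15e-06, and 0.351 as the adjusted p with an estimated correlation). In that list Krt77, Krt23 (-2.03 ± 0.50) and Krt79 (-0.90 ± 0.26) fell adjusted over the list alone, and 13 of 16 did not pass. The median was -0.31 without Get1 -/- replicate 2 and -0.39 with the mean of probe sets. Basal keratinocyte genes had a median of -0.12 (adjusted p = 0.0156, and 0.351 as the adjusted p with an estimated correlation), with 0 of 21 members passing. The list missed the threshold without Get1 +/+ replicate 2 (adjusted p = 0.0626), without Get1 -/- replicate 2 (0.0629) and with the mean of probe sets (0.0855), and its median was -0.065 without Get1 +/+ replicate 3. Krt15 (-0.29 ± 0.13) and Col17a1 (-0.29 ± 0.15) had the smallest p there.

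Genes of the cornified envelope moved both ways. In the list of envelope proteins 19 of 20 members were lower, with a median of -0.50 (adjusted p = 1.49e-08, and adjusted p = 0.351 with an estimated correlation), or -0.26 without Get1 -/- replicate 1. Adjusted over the list alone, periplakin Ppl (-0.86 ± 0.18), Krtdap (-0.45 ± 0.12) and S100a14 (-0.60 ± 0.18) fell and Rptn rose. In the Lce family, late envelope proteins, 12 of 13 members were lower, with a median of -0.66 (adjusted p = 1.74e-05, and 0.354 as the adjusted p with an estimated correlation), or -0.43 without Get1 +/+ replicate 2 and -0.34 without Get1 -/- replicate 1. There Lce1m (-1.98 ± 0.43) and Lce1c (-1.10 ± 0.30) fell and Lce3c rose, adjusted over the list alone. Of 5 measured Sprr genes 3 were higher, with a median of 0.58 (adjusted p = 0.0316, and 0.351 as the adjusted p with an estimated correlation), and Sprr2d alone passed. The list missed the threshold without Get1 +/+ replicate 1 (0.155), without Get1 +/+ replicate 3 (0.189, median 0.14), without Get1 -/- replicate 2 (0.155) and with array weights (0.218, median 0.25). Crosslinking enzymes and proteases had a median of -0.36 (adjusted p = 3.01e-06, and 0.351 as the adjusted p with an estimated correlation). None of their 27 members passed adjusted over the list alone, and transglutaminase Tgm1 changed by -0.89 ± 0.30.

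The stress keratins and alarmins did not shift as a list (camera adjusted p = 0.628), with a median of -0.20 and a mean of 0.48, so median and mean differed in sign. Without Get1 +/+ replicate 2 the median was 0.11 and the list passed (adjusted p = 0.0264). Members went both ways, and the list was 1 of the 4 that passed fry for change in either direction (adjusted p = 9.48e-05), which Krt6b may carry. Adjusted over the list alone 6 rose, namely Krt6b, Krt16, Krt6a (2.48 ± 0.59) and the alarmin genes S100a8 (2.27 ± 0.68), S100a9 (2.37 ± 0.51) and Lcn2 (2.33 ± 0.71). Gasdermin A (Gsdma, -1.80 ± 0.38) and the EGF receptor ligands Btc (-1.14 ± 0.32) and Tgfa (-0.82 ± 0.28) fell. The other kept probe sets of Krt6a, Gsdma and Btc followed at an unadjusted p under 0.05 (limma), and that of Tgfa did not. The arrays also split by the signal of the beta-actin control probe set, given at the end. On the 3 arrays with a high actin control, S100a8 differed between genotypes by 4.09 and on the others by 0.19, S100a9 by 3.85 and 0.80, Krt6a by 3.62 and 1.14 and Lcn2 by 3.49 and 0.72. Krt6b (7.16 and 7.04) and Krt16 (2.82 and 2.44) differed by similar amounts on both sets of arrays. Each of these differences rests on 1 array of a genotype, Get1 -/- replicate 1 among the former and Get1 +/+ replicate 3 among the latter.

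Epidermal transcription factors had a median of -0.20 (adjusted p = 1.2e-05, and 0.351 as the adjusted p with an estimated correlation), and only Hopx passed adjusted over the list alone. Pou2f3 changed by -0.80 ± 0.21 and Prdm1 by -0.40 ± 0.15. Hair follicle genes had a median of -0.28 (adjusted p = 9.05e-06, and 0.351 as the adjusted p with an estimated correlation), with 0 of 30 passing. Among them Krt73 differed by -2.46 on the arrays with a low actin control and by -0.26 on the others, where Get1 +/+ replicate 3 and Get1 -/- replicate 1 were again the single arrays of their genotype. Immediate early and heat shock genes, which respond to tissue handling, had a median of -0.43 (adjusted p = 9.4e-06, and 0.351 as the adjusted p with an estimated correlation). Without Get1 +/+ replicate 2 the median was -0.11 and the list missed the threshold (adjusted p = 0.16), and without Get1 -/- replicate 1 the median was -0.28. Egr1 ranged widely in Get1 +/+ skin (4999 ± 3722, against 1808 ± 926). Proliferation genes (median 0.08, adjusted p = 0.0591) did not pass, but passed without Get1 +/+ replicate 1 (0.0374) or 3 (0.0474), without Get1 -/- replicate 1 (0.0162) or 3 (0.0224), with no filter (0.0266) and with the mean of probe sets (0.0445). Without Get1 +/+ replicate 2 the median was 0.018 (adjusted p = 0.188), and without Get1 -/- replicate 2 it was 0.058 (0.38).

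Among genes of other cell types, skeletal muscle genes had a median log2 change of 0.42, with 42 of 46 higher (adjusted p = 1.61e-09, and adjusted p = 0.4 with an estimated correlation). The median was 0.17 without Get1 +/+ replicate 2, 0.69 without Get1 +/+ replicate 1, 0.67 without Get1 -/- replicate 2 and 0.65 with array weights. Myh7 (1.35 ± 0.32), Trim63 (0.83 ± 0.21), Tnnc1 (1.00 ± 0.25) and Tnni1 (0.95 ± 0.25) rose adjusted over the list alone, and Trim63 too lies within 100 genes of Grhl3. Macrophage and lymphoid genes had a median of 0.39, with 23 of 27 higher (adjusted p = 8.13e-08, and 0.351 as the adjusted p with an estimated correlation), and the leukocyte gene Ptprc rose adjusted over the list alone (0.99 ± 0.21). C1qa of this list (0.64 ± 0.19) lies within 100 genes of Grhl3 as well. Mast cell genes (median 0.25, adjusted p = 0.00699, and 0.4 as the adjusted p with an estimated correlation) and interferon response genes (0.30, adjusted p = 0.0086, and 0.454 likewise) were placed higher. The mast cell list missed the threshold without Get1 +/+ replicate 3 (0.372, median 0.15) or Get1 -/- replicate 3 (0.0718). The interferon list missed it without Get1 +/+ replicate 1 (0.125) or 2 (0.068, median 0.16), without Get1 -/- replicate 1 (0.205, median 0.12) or 2 (0.0629), and with array weights (0.0734). Melanocyte genes were placed lower (-0.19, adjusted p = 0.0227, and 0.4 as the adjusted p with an estimated correlation). They missed the threshold without Get1 +/+ replicate 3 (0.235, median -0.12), without Get1 -/- replicate 2 (0.0629) or 3 (0.0649), with the stricter filter (0.0987, median -0.38) and with the mean of probe sets (0.0614), and their median was -0.29 and -0.34 without Get1 +/+ replicates 1 and 2 and -0.29 with no filter. Dermal fibroblast (0.02), endothelium (0.13), adipocyte (0.13), erythroid (0.05) and Schwann cell genes (0.18) did not pass with all 6 arrays. With 1 array left out their medians ran from -0.068 to 0.13, 0.053 to 0.26, 0.015 to 0.29, 0.027 to 0.24 and 0.054 to 0.26, in that order. Leaving out 1 array brought fibroblast genes past the threshold without Get1 +/+ replicate 1 (0.0148) or Get1 -/- replicate 1 (0.0473), adipocyte genes without Get1 +/+ replicate 2 (0.00981, median 0.29) or Get1 -/- replicate 1 (0.00212), and endothelium genes without Get1 +/+ replicate 1 (0.0357) or Get1 -/- replicate 1 (0.0421) or 2 (0.0167). Endothelium genes also passed with no filter (0.0266), the stricter filter (0.0308), array weights (0.0167) and the mean of probe sets (0.0313).

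**Figure D2:**
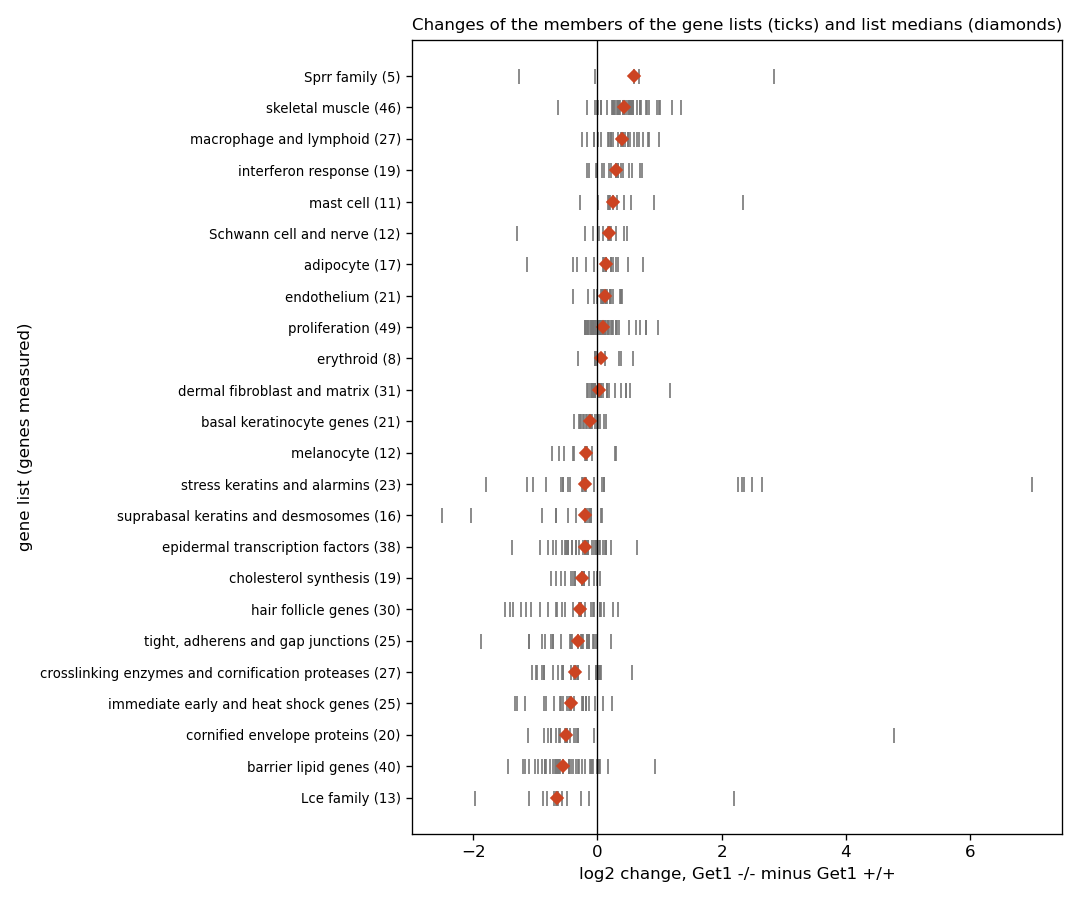
Log2 change (Get1 -/- minus Get1 +/+) of each measured member (ticks) and the median (diamonds) of the tested gene lists, except 1 that is not reported here. Medians run from -0.66 for the Lce family to 0.58 for the Sprr family, and Rptn, Lce3c and Krt6b lie far from the medians of their lists.

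The arrays differed in ways that genotype does not describe. The middle beta-actin control read between 18407 and 19858 on Get1 +/+ replicates 1 and 2 and Get1 -/- replicate 1, and between 10118 and 13060 on the other 3 arrays. Ratios of 3' to 5' signal ran from 1.354 to 1.494 for actin and from 0.692 to 0.844 for Gapdh. The first principal component held 36.3% of the variance and did not separate the genotypes. Get1 +/+ replicate 1 (-15.8) lay among the Get1 -/- arrays (-41.7 to -3.16), away from Get1 +/+ replicates 2 (46.3) and 3 (35.9). Without this array the counts rose to 25 probe sets and 120 genes. Xist was high (13611 to 15077) on Get1 +/+ replicate 2 and Get1 -/- replicates 1 and 3, and low (122 to 202) on the others, where the Y-linked Eif2s3y was high (907 to 1906, against 9.82 to 50.6), so each genotype held embryos of both sexes.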

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

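The signal of the phe spike-in control, a bacterial transcript added to the samples and outside the comparisons, was flagged because it was higher on all 3 Get1 -/- arrays than on all 3 Get1 +/+ arrays. Its mean was 552 ± 21.7 against 385 ± 103, a ratio of 1.43. The dap, lys and thr spike-in controls had ratios of 1.31, 1.35 and 1.36, and their genotypes overlapped.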

How the results depend on the processing

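The block on the split of the control probe sets and the fit without neighbours of Grhl3 were chosen after seeing the data. Krt6b, Rptn and Sprr2d passed in all 17 alternatives of the gene table, with log2 changes of 6.67 to 7.21, 4.37 to 5.12 and 2.61 to 3.00, and adjusted p up to 0.000104, 0.0237 and 0.0229. Gsta2 passed in 16 of 17 (adjusted p 0.00333 to 0.0682) and Krt77 in 8 of 16 (0.00816 to 0.375). Grhl3 was lower in all 16 alternatives, by -1.23 to -0.74, and passed in 0 (adjusted p 0.0737 to 0.976). Leaving out 1 array gave 4 to 25 probe sets (3 to 19 higher, 1 to 6 lower), 3 to 120 genes (3 to 96 higher, 0 to 24 lower) and 14 to 20 lists (4 to 8 higher, 10 to 12 lower). The highest counts of probe sets and genes came without Get1 +/+ replicate 1. The replicate block gave 35 probe sets (12 higher, 23 lower) and 44 genes (12 higher, 32 lower), including the 6 and 5 called without it, and changed the call of 0 lists. All 6 arrays correlated best with their own number over the kept probe sets, and 2 of 6 over the genes. Array weights gave 8 genes, 5 of them lower, and 4 lower probe sets. The offset gave 5 higher genes. The count of lower genes was 1 with quantile normalization, no filter, the stricter filter and the control split as a block, and the count of lower probe sets was 1 with eBayes without the trend and with that block. A threshold of 0.1 gave 11 probe sets (7 higher, 4 lower) and 12 genes (5 higher, 7 lower). Camera with an estimated correlation and fry called 0 lists, 0 higher and 0 lower. Estimated correlations ran from -0.03 to 0.7, against the preset 0.01. The Sprr family (-0.03) lost its call too, with an unadjusted camera p of 0.0789 against 0.0215 at the preset correlation. Members that vary together therefore do not account for every loss. With an estimated correlation, camera also takes its degrees of freedom from the 6 arrays and not from the number of genes, which raises p. How much of each loss is due to this was not tested. The median of the stress keratins and alarmins ran from -0.407 to 0.114 when 1 array was left out, against -0.20, and the list turned and passed without Get1 +/+ replicate 2. Uncalled signs that turned are not counted as changes. Where silent, Eif2s3y read 9.82 to 50.6 and Xist 122 to 202, so Krt6b and Rptn in Get1 +/+ skin (146 and 143) may lie at background, which limits the size of their folds.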

Other observations

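The tests of the neighbours of Grhl3, of the share of epidermis, of the splits for probe sets and of the control split for the keratins were chosen after the result was seen. With the replicate block, further genes outside the lists passed, chosen here after their values were seen. Higher in Get1 -/- skin were the chitinase-like gene Chil1 (log2 change 2.23 ± 0.27, SE, adjusted p = 0.0353), the chitinase gene Chit1 (1.34 ± 0.17, adjusted p = 0.0365) and Fetub (2.23 ± 0.28, adjusted p = 0.0365). Lower were the histidine ammonia-lyase Hal (-1.32 ± 0.12, adjusted p = 0.0134), the DNase of cornifying cells Dnase1l2 (-1.66 ± 0.20, adjusted p = 0.0306) and the zinc transporter Slc39a2 (-1.65 ± 0.22, adjusted p = 0.0413). None of these passed in the unblocked fit of all 6 arrays.

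The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The genotypes gave 6 probe sets, the most of the 10 and reached by no other split, and the highest other split gave 5. That split followed the high Xist signal. For genes the genotypes gave 5, reached by no other split, and the highest other gave 2. For gene lists at the preset correlation the genotypes gave 17, and the other splits gave from 3 to 18. A camera call at the preset correlation therefore does not by itself set the genotypes apart from other groupings. With the genotypes counted in, 2 of the 10 splits gave at least 17, the highest other giving 18. This other split set Get1 +/+ replicate 1 and Get1 -/- replicates 1 and 3 against the rest and had 2760 probe sets at an unadjusted p under 0.05, which points to a structure of the arrays that genotype does not describe. Among the 4 splits that part all 3 same-numbered pairs, the others gave 1, 5 and 0 probe sets.

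Barrier lipid genes were lower in Get1 -/- skin, with a median shift of -0.55, and -0.32 without Get1 +/+ replicate 2. With the control split as a block it was -0.63, which argues against that split as the cause. After quantile normalization it was -0.56, which argues against differences in the shape of the arrays' signal distributions alone. The median change of all genes was already 0.0076 as deposited, so quantile normalization could not reveal a scaling shift shared by all genes, which stays open. Under a smaller share of epidermis in the Get1 -/- samples basal keratinocyte genes would fall as far, and the mean shift of the lipid genes minus that of the basal genes was -0.382 ± 0.255 (SE) with overlapping genotypes, or -0.382 ± 0.0702 within same-numbered mice (lower in 3 of 3). That share would also raise other cell types alike, and skeletal muscle minus dermal fibroblast genes gave 0.346 ± 0.267, or 0.346 ± 0.0747 within same-numbered mice (higher in 3 of 3), and macrophage and lymphoid minus fibroblast genes 0.261 ± 0.194, or 0.261 ± 0.271. These scores come from the genes, over which 1 of the 3 same-numbered pairs passed the limit for pairing. The paired values of the lipid and muscle genes therefore cannot decide about that share, and the unpaired ones do not decide either, so it stays open. Camera with an estimated correlation did not call the list (adjusted p = 0.351), and no biological explanation was tested.

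Krt6b, Krt6a, Krt16 and Krt12 were higher in Get1 -/- skin. Changes of the added markers were taken with the offset named among the alternatives, which shrinks changes at low signals. Prtn3, with mean signals of 20.2 in Get1 +/+ and 56.8 in Get1 -/- skin, thus read 0.604. Over 16 measured markers of other epithelium the median change was -0.143 and the highest 0.331. Over 13 measured neutrophil markers the median was -0.0296 and the highest 0.849 (Mmp8). Only 3 and 4 of the markers reached the filter limit, and both tests rest on the other probe sets being able to respond. The markers of other epithelium argue against such cells only as far as their probe sets can respond. The neutrophil markers cannot decide about the 4 keratins, which are genes of epithelium and not of neutrophils. With the control split as a block the smallest of the 4 changes was 2.38, which argues against that split as the cause. Cross-hybridisation between keratins stays open, since probe sequences were not used here, and an effect of the genotype on keratinocytes may account for the rise only as a hypothesis.

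Genes near Grhl3 changed more often than others. Of the 76 tested among the 100 RefSeq genes on either side, 9 (11.8%) had an unadjusted p under 0.01, against 1.75% of 10649 on other chromosomes. As many were found in 0.139% of 2153 overlapping runs of the same length elsewhere, at most 11, so such runs were rare. The runs were not matched for the number of genes tested. Their rarity cannot show whether the genes near Grhl3 are expressed together, which stays open. Trim63 and C1qa, changed there, belong to the muscle and macrophage lists, which were placed higher as a whole. A candidate explanation is sequence variants carried along with the targeted locus, which could alter hybridisation of single probe sets. Of 7 sister probe sets of the changed ones 28.6% followed (95% Wilson interval 8.22 to 64.1), against 49.2% (42 to 56.4) elsewhere, too few to decide, and an effect of the lost gene on its neighbours was not tested. Farther along the chromosome, Khdrbs1 and Ptp4a2 each had a single probe set that differed, by -2.50 and 1.22, while their other kept probe sets changed by at most 0.50 in size.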
